A study of Mus musculus with 6 samples.

How the data were processed

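miRNA sequencing of extracellular vesicles from mouse brain was analysed in 6 libraries, 3 labelled SE and 3 labelled CON. Per the labels' protocols, RNA was extracted with a column kit that included DNase treatment, and libraries were made with the QIAseq miRNA kit, which can carry molecular identifiers. Whether identifiers were used for counting is not given in the sources used here, nor are the aligner, the counter or the miRNA annotation. Per the submitters' processing notes, the genome build was mm9 and DESeq2 was among the tools, with no role or version stated.

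The authors' deposited RPM table holds RPM values, reads scaled to a fixed total of the reads assigned to its 1926 listed miRNAs. Names that share an entry, such as miR-23a-3p and miR-23b-3p, were counted together by the authors in 35 merged names, per the file headers and names. Every RPM value was a whole multiple, within 0.01 reads, of what 1 read was worth in its column, on the reading that the lowest value of each column stands for 2 reads. Depths were taken from these steps. Counts from this step were used for depth, for floors of 3 counts and for an added alternative. The authors' deposited table of fold changes covers 775 miRNAs. Per the file headers it gives a base mean of normalized counts over the libraries, a log2 fold change with its standard error, a Wald score, and p-values with adjusted p-values. It was copied and not refitted. Its adjusted p equals a Benjamini-Hochberg adjustment of its own p-values over 772 miRNAs, and 3 miRNAs have no p-value.

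The rows of the CON columns had to be put back under their miRNA names, a step chosen after the data were examined. In the deposited RPM table both the CON means and the SE means descend down the file, with 0 miRNAs out of order in either. For each miRNA, 6 times the base mean minus the normalized SE reads gives the total of the second group in the authors' deposited table. That total was above 0 for 687 miRNAs and at 0 for 88, and 687 rows of the CON columns were above 0. After 3 size factors were fitted to the CON columns, each of the 687 totals matched a CON row within a relative tolerance of 1e-05, with a largest relative difference of 3.47e-09. The match had 1 candidate row for 597 miRNAs and several rows with identical reads for the other 90, so the reads per miRNA are the same whichever is taken. With the CON size factors exchanged between columns in 5 ways, at most 3 of the 312 miRNAs with a total of at least 150 matched. The size factors were 1.77, 0.863 and 0.895 for SE replicates 1, 2 and 3, and 0.916, 0.821 and 1.03 for CON replicates 1, 2 and 3. The name changed for 665 rows and stayed for 22, and of the 290 miRNAs with a mean of at least 10 RPM, 270 received another row. The columns' groups were taken from their names, never from values.

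The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(RPM + 1), with group as the factor, for miRNAs with a mean of at least 10 RPM over the 6 libraries. Calls are two-sided with a Benjamini-Hochberg adjusted p under 0.05. A count test was not the main test because RPM values are not counts. 23 lists of miRNAs were fixed before the data were examined, along with the tests and most alternatives, and the 20 with at least 3 tested members were tested with camera at a preset correlation of 0.01. The share of reads in the 10 most abundant miRNAs was compared with an exact permutation test over 10 splits. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

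Named miRNAs followed a rule fixed before the data were examined. It takes the 12 with the largest rise and the 12 with the largest fall among calls whose SE and CON values do not overlap, filled up by unadjusted p to 12 in a direction and said not to pass. It adds the 5 most abundant miRNAs, the members of each list that pass or otherwise up to its 4 most abundant, 20 miRNAs named in advance, and up to 5 rising and 5 falling miRNAs with the smallest adjusted p in the authors' deposited table. miR-872-3p was named after its values were seen.

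The alternatives were pseudocounts of 0.5 and 5 RPM, no filter and a filter of 50 RPM, median-of-ratios scaling, quantile normalization, limma without trend, robust limma, the replicate number as a block, an adjusted p under 0.1, each library left out in turn, an estimated correlation and fry for the lists, and the 5 or 50 most abundant miRNAs for the share. Alternatives added after the data were examined were limma-voom on the recovered reads, the CON rows under the names as deposited, and a base mean of at least 50 for the authors' calls.

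limma was tested on simulated counts for 290 miRNAs with a dispersion of 0.04, 5 runs and 30 changed miRNAs per fold in each run. In the comparison of SE with CON it recovered 79.3% of miRNAs changed by 2-fold and 94.7% of those changed by 4-fold, and called 1.66% of unchanged ones. camera found the Dlk1-Dio3 list, the largest with 53 tested members, in 20 of 20 runs with its members shifted by 0.5 log2 units. In 20 runs without a shift it called this list 0 times and other lists 0.1 times per run. The simulated miRNAs were independent. In the data the estimated correlation ran from -0.391 in the liver list to 0.664 in the vascular list. These runs therefore do not show how often camera finds or miscalls lists in the data.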

Results

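MicroRNAs (miRNAs), short RNAs that bind messenger RNAs and lower their translation, were sequenced from extracellular vesicles of mouse brain. Extracellular vesicles are membrane-bound particles that cells release. The 6 libraries fall into 2 groups of 3 by their labels: vesicles from mice after status epilepticus (SE), a prolonged seizure, and vesicles from control mice (CON). The series title gives a time of 24 hr. The comparison asks which miRNAs differ in abundance between brain vesicles after status epilepticus and control vesicles. The libraries held 10845434, 6016533 and 6690244 miRNA reads in SE replicates 1, 2 and 3, and 5593880, 5482407 and 6504884 in CON replicates 1, 2 and 3. A value of 0 in a library allows up to 0.277 to 0.547 RPM, the level of 3 reads, and such floors cover counting error only. The lowest value above 0 stood for 2 reads in each library, so a listed 0 may hide a single read. The floors do not allow for that. RPM are the reads of a miRNA scaled to a fixed total per library. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

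In the authors' deposited RPM table, the names of the miRNAs went with the SE columns only. Over the 704 miRNAs above 0, 0 of 247359 pairs stood in opposite order in the CON mean and the SE mean, against 15853 to 18234 pairs in the other 9 splits of the columns. The rows of the CON columns were put back under their miRNA names with the base means of the authors' deposited table of fold changes. All 687 miRNAs of its second group matched a CON row within a relative tolerance of 1e-05. This step was chosen after the data were examined, and every CON value below is under its name as put back. With the names put back, 775 miRNAs were detected, of which 616 were detected in both groups, 88 in SE libraries alone and 71 in CON libraries alone.

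**Figure D1:**
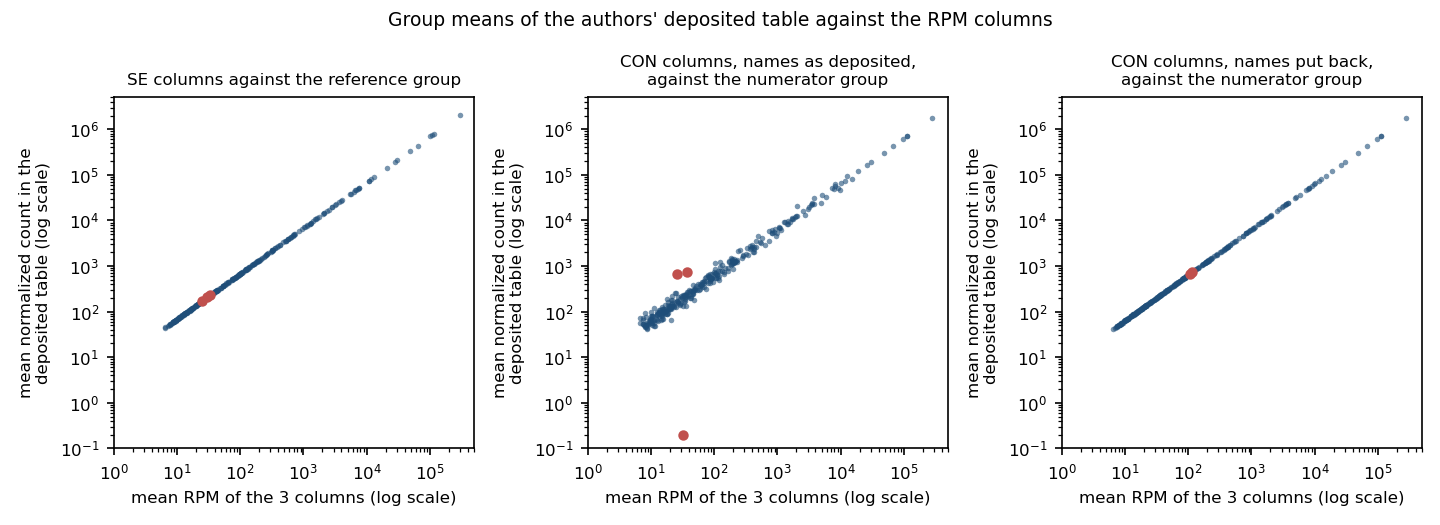
Mean normalized count per miRNA in each group of the authors' deposited table (y axis, log scale) against the mean RPM of the 3 SE or CON columns (x axis, log scale), for miRNAs with a base mean of at least 50. Each point is 1 miRNA and red points are miR-155-5p, miR-21a-5p and miR-872-5p, the last of which has no point at right because its CON value is 0. The SD of the log2 difference is 0.0130 for the SE columns, 0.614 for the CON columns with the names as deposited and 0.0611 with the names put back. The last value is not independent evidence, since the names were put back with base means of the same deposited table. With the names as deposited, the largest log2 difference of the CON columns, 9.40, is that of miR-872-5p and raises their SD.

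The vesicle libraries consisted mostly of let-7 miRNAs, a family of regulators of developmental timing and cell proliferation. The let-7 family took 80.1% ± 1.35 (SD, n = 3) of the reads in SE libraries and 78.3% ± 0.943 (SD, n = 3) in CON libraries. The 5 most abundant miRNAs were let-7c-5p, let-7b-5p, let-7f-5p, let-7a-5p and let-7g-5p. let-7c-5p alone stood at 297960 RPM in SE and 283286 RPM in CON libraries, a log2 difference of 0.07 (SE 0.07) that did not pass. Here and below, SE in parentheses after a log2 value is its standard error. The 10 most abundant miRNAs took 82.9% ± 1.28 (SD, n = 3) of the reads in SE libraries and 81.3% ± 0.970 (SD, n = 3) in CON libraries. The difference of 1.67 percentage points had p = 0.2 in an exact two-sided permutation test, in which 3 libraries against 3 cannot give a p below 0.1.

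3 miRNAs differed between the groups. miR-872-5p was detected at 29.9 RPM ± 6.19 (SD, n = 3) in the SE libraries, with 175 to 288 reads each, and at 0 in all 3 CON libraries. That is at least 171-fold higher in SE libraries, from 686 reads pooled over the SE libraries and a CON floor of 3 reads over the group. This bound takes each CON 0 as no reads. The CON 0 is not listed under this name. It follows from the put-back step, in which the second-group total of miR-872-5p was at 0. With the names as deposited, the CON columns gave a mean of 31.8 RPM. miR-155-5p, a product of macrophages, microglia and lymphocytes that is induced by inflammatory signals, fell from 105 RPM ± 5.84 (SD, n = 3) in CON to 25.3 RPM ± 3.52 (SD, n = 3) in SE libraries, which is 4.16-fold lower. miR-21a-5p, which is induced in reactive glia and in many injured tissues, fell from 116 RPM ± 32.5 (SD, n = 3) to 33.8 RPM ± 2.11 (SD, n = 3), which is 3.44-fold lower. All 3 SE values lay on the same side of all 3 CON values for each of these miRNAs. Directions here and below follow the labels SE and CON of the columns, and no value in the sources used here checks those labels: an exchange of the names between the 2 sets of columns would turn each of them.

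**Figure D2:**
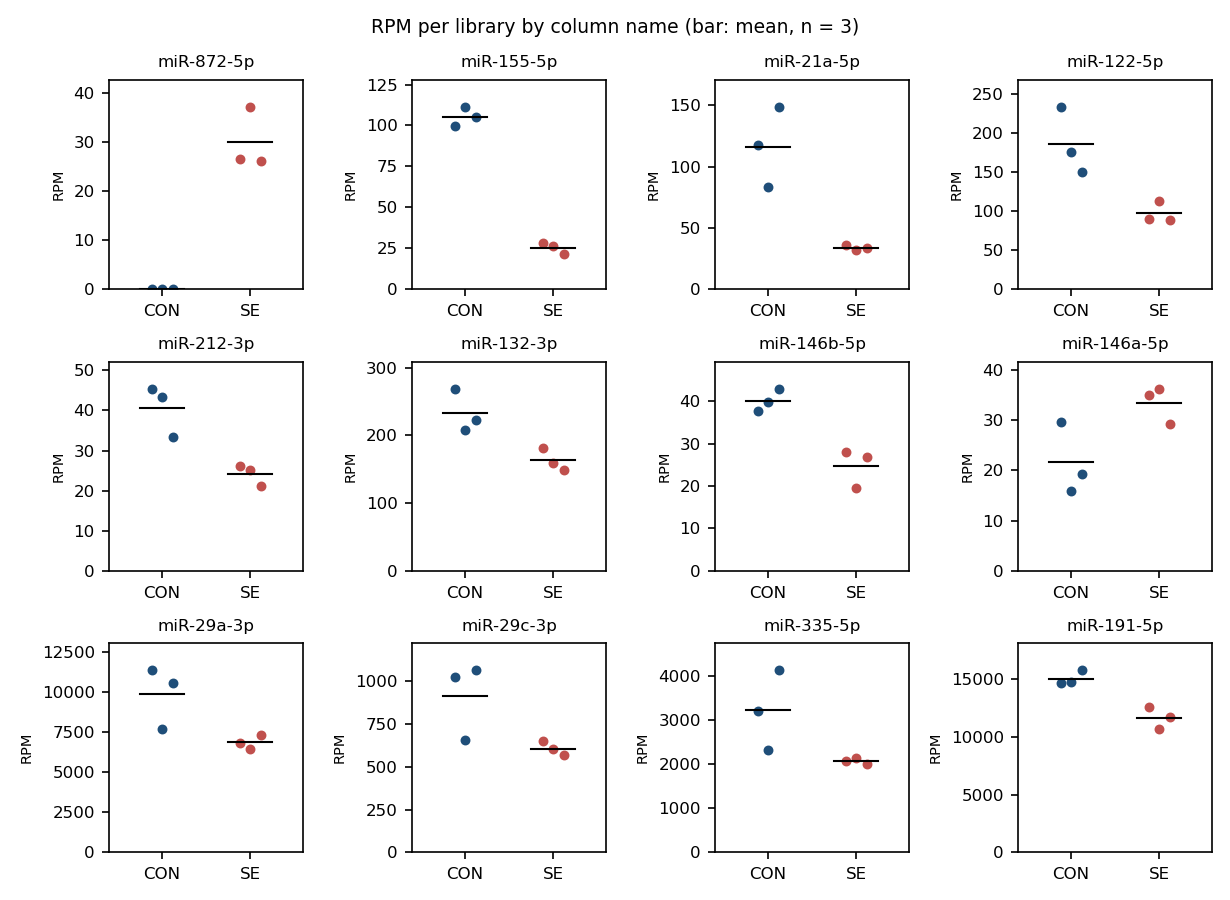
RPM of 12 miRNAs in each library (y axis, linear and starting at 0), by the group named in the label, with the mean of 3 libraries as a bar. miR-872-5p is at 0 in the 3 CON libraries, and miR-155-5p and miR-21a-5p are lower in every SE library than in every CON library. The other miRNAs shown did not pass the test.

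These 3 calls come from limma-trend on log2(RPM + 1), a scale that understates the change of low miRNAs, over 290 miRNAs with a mean of at least 10 RPM. limma gave a log2 fold change, SE over CON, of 4.93 (SE 0.33) and an adjusted p of 7.28e-09 for miR-872-5p. With CON at 0 the size of this value depends on the pseudocount. It was 5.91 with 0.5 RPM, 2.79 with 5 RPM and 8.42 by limma-voom. limma-trend gave -2.02 (SE 0.21) and 4.36e-06 for miR-155-5p, and -1.72 (SE 0.23) and 1.05e-04 for miR-21a-5p. At an unadjusted p under 0.05 there were 27 miRNAs, 5 higher and 22 lower in SE libraries, where 14.5 are expected by chance. With median-of-ratios scaling and with quantile normalization there were 9 higher and 14 lower. The count of 27 was 17 without CON replicate 1, 46 without CON replicate 2 and 15 without SE replicate 2. The SE and CON values did not overlap for 43 of the 290 miRNAs, 4 higher and 39 lower in SE libraries, where chance gives 10%. These chance figures are means and do not give the spread that correlated miRNAs would have. The median log2 fold change of all 290 was -0.07, and 0.03 with median-of-ratios scaling. Without CON replicate 2 the count of calls was 6, with miR-29a-3p, miR-29c-3p and miR-335-5p added, and without CON replicate 3 it was 5, with miR-122-5p and miR-3093-3p added. With the CON rows under the names as deposited the count was 0 of 289, with 2 miRNAs at an unadjusted p under 0.05.

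miR-122-5p, the dominant miRNA of hepatocytes, came next. It stood at 97.5 RPM ± 13.99 (SD, n = 3) in SE and 186 RPM ± 42.5 (SD, n = 3) in CON libraries, a log2 fold change of -0.91 (SE 0.22) with a limma adjusted p of 0.0504. The other lower miRNAs with the smallest unadjusted p, none of which passed, were miR-29a-3p (log2 fold change -0.51), miR-335-5p (-0.60), miR-212-3p (-0.72), miR-191-5p (-0.37), miR-146b-5p (-0.69), miR-1983 (-0.54), miR-376b-3p (-0.58), miR-1264-3p (-0.70) and miR-29c-3p (-0.56). Their limma adjusted p ran from 0.191 to 0.301. On the higher side, miR-872-5p was followed by miR-3093-3p (1.78), miR-146a-5p (0.65), miR-1224-5p (0.64), miR-323-5p (0.58), miR-92b-5p (0.47), miR-342-5p (0.37), miR-3097-5p (0.41), miR-330-5p (0.36), miR-485-5p (0.45), miR-3099-3p (0.36) and miR-1198-5p (0.38). None of these 11 passed, with limma adjusted p from 0.385 to 0.762. miR-3093-3p was at 0 in CON replicate 1 and at 14.6 to 25.7 RPM in the other 5 libraries. Quantile normalization moved some of these values in either direction, such as 1.07 for miR-3093-3p and 0.72 for miR-323-5p. Single libraries carried much of several of the values that did not pass. Without CON replicate 1 the log2 fold change was 0.44 for miR-3093-3p, 0.26 for miR-3097-5p, 0.22 for miR-485-5p and 0.14 for miR-3099-3p. Without CON replicate 2 it was 0.71 for miR-485-5p. Without CON replicate 3 it was 0.28 for miR-1224-5p, 0.26 for miR-92b-5p, 0.19 for miR-342-5p and -0.40 for miR-335-5p. Without SE replicate 1 it was 0.36 for miR-323-5p, 0.21 for miR-330-5p, 0.16 for miR-485-5p and 0.19 for miR-3099-3p, and without SE replicate 2 it was 0.37 for miR-1224-5p and 0.67 for miR-485-5p.

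Of 12 miRNAs known to respond to neuronal activity, 10 were tested and 0 passed over all miRNAs tested by limma. Adjusted over the list alone, 2 passed, miR-335-5p and miR-212-3p, both lower in SE libraries, and miR-132-3p did not. Here and below, an adjustment over a list alone was not corrected for the number of lists, some of which share members. The tandem pair miR-132-3p and miR-212-3p, which is transcribed downstream of the activity-regulated factor CREB, had log2 fold changes of -0.51 (SE 0.20) and -0.72 (SE 0.23), with limma adjusted p of 0.393 and 0.231. miR-134-5p, which acts on dendritic spine size, had 0.08 (SE 0.23). miR-26a-5p, miR-335-5p, miR-181a-5p and miR-324-5p were the most abundant members. The list of miRNAs reported repeatedly after status epilepticus or in epilepsy had 22 tested members, of which miR-155-5p and miR-21a-5p fell. Adjusted over the list alone, 3 of the 22 passed: miR-155-5p, miR-21a-5p and miR-212-3p. Its most abundant members were miR-139-5p, miR-129-5p, miR-187-3p and miR-23a-3p/23b-3p, and miR-34a-5p had a log2 fold change of -0.14 (SE 0.19).

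Of 11 tested miRNAs of inflammatory signalling and reactive glia, 2 fell, again miR-155-5p and miR-21a-5p. Adjusted over the list alone, 3 passed: miR-155-5p, miR-21a-5p and miR-146b-5p, each lower in SE libraries. The NF-kB targets miR-146a-5p and miR-146b-5p had log2 fold changes of opposite sign, 0.65 (SE 0.26) and -0.69 (SE 0.23). Neither passed over all miRNAs tested. Of 7 tested miRNAs of microglia and leukocytes, miR-155-5p fell. Adjusted over the list alone, 3 passed: miR-155-5p and miR-191-5p, lower in SE libraries, and miR-146a-5p, higher in SE libraries. miR-146a-5p did not pass in the larger inflammation and epilepsy lists, which also hold it, and its SE and CON values overlapped. miR-191-5p, the most abundant of them, stood at 11651 RPM in SE and 15016 RPM in CON libraries. The myeloid miR-142a-3p and miR-223-3p lay under the filter, at 9.68 RPM ± 4.41 and 6.24 RPM ± 2.35 (SD, n = 3) in SE and 10.3 RPM ± 5.34 and 6.76 RPM ± 4.16 (SD, n = 3) in CON libraries.

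miRNAs enriched in neurons, 20 of them tested, made up 6.49% ± 0.402 (SD, n = 3) of the reads in SE and 6.57% ± 0.396 (SD, n = 3) in CON libraries, and 0 of them passed, alone or over all miRNAs. They were led by miR-7a-5p, miR-7b-5p, miR-127-3p and miR-9-5p. The log2 fold changes were 0.16 (SE 0.20) for miR-124-3p, -0.33 (SE 0.16) for miR-128-3p and -0.24 (SE 0.14) for miR-9-5p. The astrocyte list held 1.37% ± 0.0486 (SD, n = 3) of the reads in SE and 1.77% ± 0.268 (SD, n = 3) in CON libraries. 0 of its 9 tested members passed and 1 did when adjusted over the list alone, and miR-29a-3p, miR-24-3p, miR-143-3p and miR-29c-3p led it. In the oligodendrocyte list, 0 of 3 tested members passed, and miR-338-3p, which acts in myelinating cells, had -0.49 (SE 0.22). miR-219a-5p was at 0.292 RPM in SE and 0 in CON libraries.

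Lists of blood, vessels, choroid plexus, liver and muscle describe other possible contents of the preparations. The red cell miRNA miR-451a was at 0 in SE libraries and 0.307 RPM in CON libraries, and miR-486a-5p/486b-5p had a log2 fold change of -0.06 (SE 0.27), which was 0.04 with median-of-ratios scaling. 0 of the 5 tested erythrocyte members passed, led by miR-16-5p and miR-185-5p. The endothelial miR-126a-3p, which led the 7 tested vascular members, had -0.26 (SE 0.15), and 0 of them passed. The choroid plexus miRNA miR-204-5p stood at 400.0 RPM ± 153 (SD, n = 3) in SE and 380 RPM ± 79.9 (SD, n = 3) in CON libraries, a log2 fold change of 0.03 (SE 0.26), and 0 of the 8 tested choroid plexus and ependyma members passed. The liver list, with 3 tested members, had 0 that passed and 1, miR-122-5p, when adjusted over the list alone. The muscle list was led by miR-1a-3p, at 152 RPM ± 5.53 in SE and 201 RPM ± 23.99 (SD, n = 3) in CON libraries, and 0 of its 2 members over the filter passed. Adjusted over the list alone, 0 members passed in the oligodendrocyte, erythrocyte, vascular and choroid plexus lists.

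Families and clusters were described in the same way. 0 members passed over all miRNAs tested in the miR-29 family (4 tested, 2 when adjusted over the list alone), the miR-30 family (12 tested), the let-7 family (12), the miR-17~92 cluster and its paralogs (5), the miR-181 family (6), the imprinted Dlk1-Dio3 locus (53), the Sfmbt2 cluster (6), the p53-induced miR-34 family with its companions (3) and entries that overlap structural RNA (3). Adjusted over the list alone, 0 passed in each of these lists other than the miR-29 family. The miR-29 family held 0.801% ± 0.0335 (SD, n = 3) of the reads in SE and 1.16% ± 0.231 (SD, n = 3) in CON libraries. The Dlk1-Dio3 locus, led by miR-382-5p, miR-127-3p, miR-411-5p and miR-337-5p, held 2.73% ± 0.172 and 2.83% ± 0.143 (SD, n = 3). The hypoxia-induced miR-210-3p stood at 64.7 RPM ± 5.13 in SE and 65.1 RPM ± 7.51 (SD, n = 3) in CON libraries, a log2 fold change of -0.01 (SE 0.21) that was 0.10 with median-of-ratios scaling. The cluster of miR-183 and its neighbours had no member over the filter and was led by miR-182-5p, at 4.71 RPM ± 1.69 in SE and 4.80 RPM ± 3.93 (SD, n = 3) in CON libraries.

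**Figure D3:**
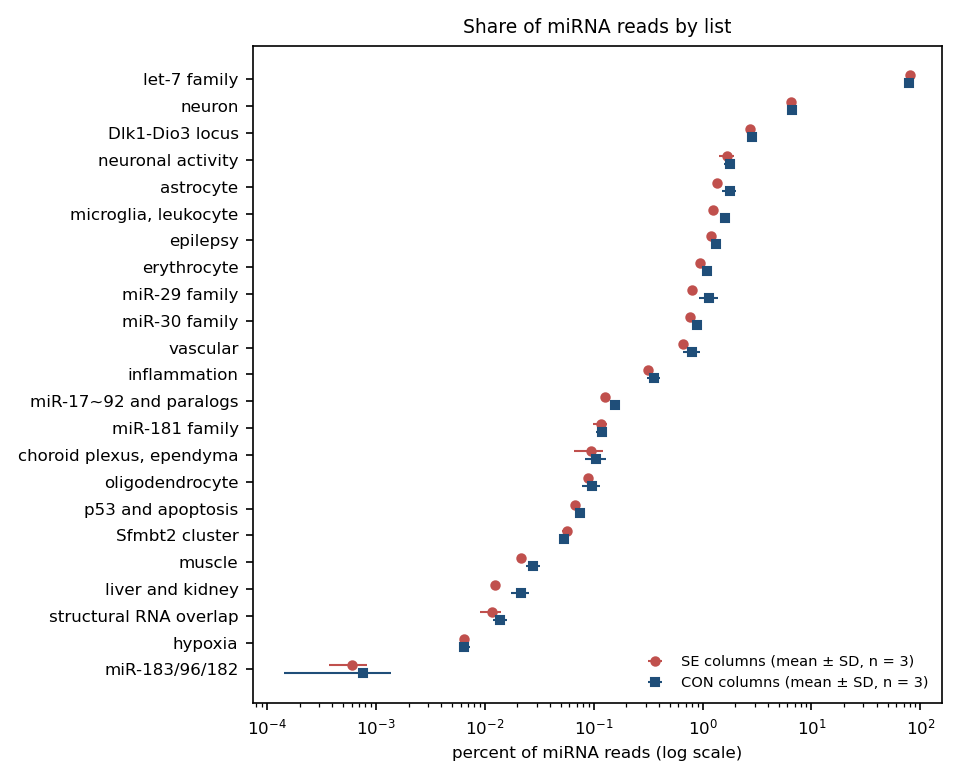
Share of all miRNA reads taken by each list (x axis, percent, log scale) in the SE libraries (red circles) and CON libraries (blue squares), as mean and SD of 3 libraries. The let-7 family took 80.1% and 78.3%, and the lists of other cell types lie at 6.57% or less.

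As sets, 0 of the 20 lists with at least 3 tested members were shifted by camera, with the lowest adjusted p at 0.315 for the epilepsy list and the miR-29 family. At an unadjusted p under 0.05 there were 2 lists, these same ones. The count was also 0 with an estimated correlation, where the lowest adjusted p was 0.832, and 0 by fry, where it was 0.103. It was 1 without the filter, the inflammation list with adjusted p = 0.0154, and 1 without CON replicate 1, the choroid plexus and ependyma list with adjusted p = 0.0171. The activity list had an adjusted p of 0.757. Median, mean and test differed in sign for the neuron, oligodendrocyte, vascular and let-7 lists.

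miR-155-5p, miR-21a-5p and miR-872-5p were also called in the authors' deposited table. The shared calls are not independent evidence, since the CON reads were put back under their names with base means of that table. That table does not name its direction, but its reference group matched the columns labelled SE by miRNA name, so a positive value stands for a higher level in the columns labelled CON. The authors' deposited table calls 8 miRNAs at an adjusted p under 0.05, 6 positive and 2 negative. Its largest statistics belong to miR-155-5p, with a log2 fold change of 1.96 (SE 0.16) and adjusted p of 3.78e-32 in the authors' deposited table, and miR-872-5p, with -10.00 (SE 1.24) and 2.97e-13. The authors' deposited table also calls miR-21a-5p (1.67, SE 0.24), its partner arm miR-21a-3p (8.48, SE 1.35), miR-132-3p (0.41, SE 0.11), miR-3080-5p (6.41, SE 1.76), miR-122-5p (0.82, SE 0.23) and miR-7004-5p (-5.96, SE 1.69). The adjusted p of miR-132-3p, miR-3080-5p, miR-122-5p and miR-7004-5p in the authors' deposited table lies between 0.0333 and 0.04004. 5 of the 8 miRNAs in the authors' deposited table have a base mean of at least 50. The next miRNA in the authors' deposited table, miR-212-3p at 0.65, had an adjusted p of 0.218 and was not called. Among the negative ones in the authors' deposited table, miR-330-5p at -0.48 and miR-146a-5p at -0.75 came next, with adjusted p of 0.440 and 0.499.

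3 of the miRNAs called in the authors' deposited table were under the filter of 10 RPM and were seen in a single group. Their lower bounds of fold are from the reads pooled over that group and a floor of 3 reads over the other group, not from the mean RPM. These bounds also take each 0, listed or put back, as no reads. miR-21a-3p stood at 9.30 RPM ± 3.15 (SD, n = 3) in CON libraries, 40 to 84 reads each and 167 in all, and at 0 in SE libraries, at least 74.6-fold lower. miR-3080-5p stood at 2.22 RPM ± 1.02 (SD, n = 3) in CON libraries and at 0 in SE libraries, at least 16.97-fold lower. miR-7004-5p stood at 1.83 RPM ± 0.333 (SD, n = 3) in SE libraries and at 0 in CON libraries, at least 10.7-fold higher. Over the 290 tested miRNAs, the sign of the CON over SE log2 fold change was the same as in the authors' deposited table for 87.6% with the names put back and for 53.1% with the names as deposited. The former figure is not independent evidence, since the names were put back with base means of the authors' deposited table.

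**Figure D4:**
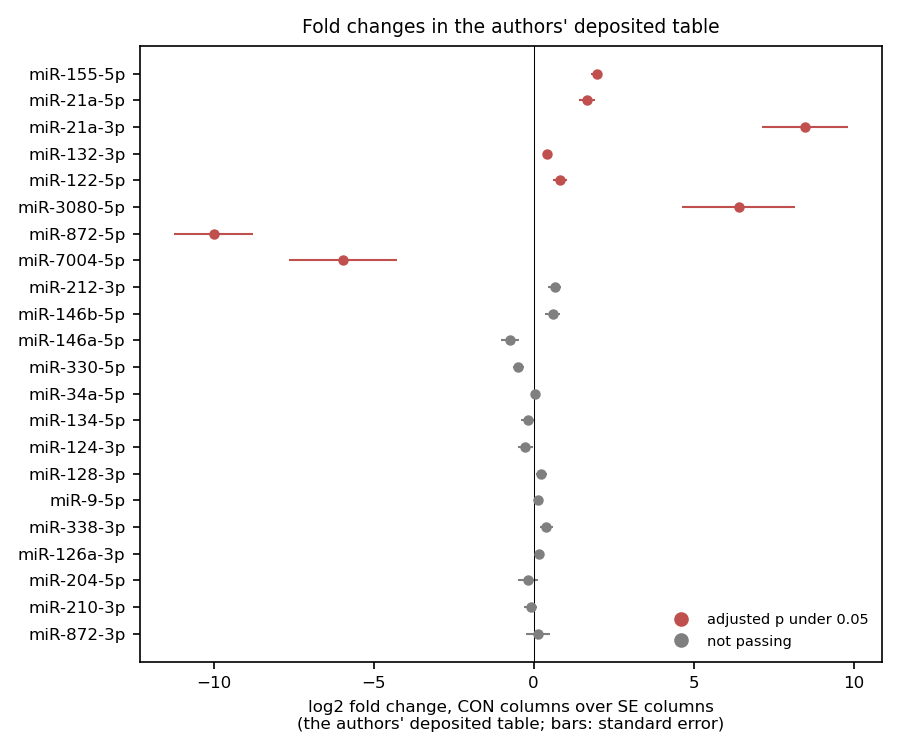
log2 fold change with its standard error in the authors' deposited table (x axis), CON columns over SE columns, for the 8 called miRNAs (red) and further named miRNAs (grey, not passing). miR-155-5p lies at 1.96 and miR-872-5p at -10.00, and miR-872-3p, the partner arm of the latter, at 0.15.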

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

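All tests in this part were chosen after the result was seen. In the authors' deposited RPM table, 71 miRNAs were listed at 0 in all 6 columns although the authors' deposited table of fold changes gives them a base mean above 0. The highest base mean among them was 29.6, for miR-21a-3p, a signal outside the values listed under that name. With the CON rows put back, each of the 71 was detected in CON libraries alone. That is fixed by the step itself, since their SE values were 0 and their base mean was above 0.

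The pattern behind this is that the miRNAs stood in the same order in the CON columns and in the SE columns. Libraries so alike that the order coincides are argued against by the other splits of the columns, the least of which had 15853 pairs of miRNAs in opposite order. CON values computed from the SE columns are argued against by the authors' deposited table, in which exactly 1 row of CON reads gave the second-group total for 312 of the 312 miRNAs with a total of at least 150. A candidate explanation is that each group of columns was sorted by its own mean and given the names of the SE columns, since 687 of 687 rows of CON reads matched a miRNA of that table. No biological explanation was tested for this pattern.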

How the results depend on the processing

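The limma-voom fit, the fits under the names as deposited and the filter on base mean were chosen after the data were examined. The count of 3 changed miRNAs stayed between 2 and 4 under the settings with the names put back and all libraries, including 3 by limma-voom, and leaving out a library gave 3 to 6. miR-155-5p and miR-21a-5p were called in 16 of 16 settings with the names put back, with highest adjusted p of 0.00183 and 0.0194, and miR-872-5p in the 15 of 15 that tested it, with 0.00103. miR-122-5p passed in 3 of 16, with adjusted p from 0.00851 to 0.369. With the names as deposited the count was 0. The count of lists, 0, became 1 without the filter and 0 to 1 when a library was left out. The authors' calls fell from 8 to 5 at a base mean of at least 50. The cause was not tested, other than CON values under other miRNAs' names as deposited, fewer miRNAs under filters and fewer samples when libraries were left out. The share of reads in the 10 most abundant miRNAs kept its direction under each setting.

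Replicate numbers did not pair the samples, with correlations of deviations of -0.415, -0.249 and 0.0447 for the same numbers, and not every library correlated best with its own number. With the replicate block the counts were 3 miRNAs and 0 lists, and the share difference was 1.67 percentage points. The edgeR and count-model alternatives were not run. The lowest value of each column stood for 2 reads, which did not meet the criterion set for recovered reads. On that reading the values were whole multiples of 1 read, and limma-voom was run on the recovered reads instead.

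Of 35 named miRNAs, 19 changed sign under at least 1 setting, 31 changes in all. Among these settings is the fit with the names as deposited, where most CON values stand under the name of another miRNA. Its sign changes come from that, and the cause of the others was not tested. With the names as deposited the log2 fold changes were -0.0888 for miR-872-5p, -0.0666 for miR-146a-5p, -0.0249 for miR-1224-5p, -0.14 for miR-323-5p, -0.16 for miR-3097-5p, -0.17 for miR-330-5p, -0.15 for miR-485-5p, -0.16 for miR-3099-3p, -0.00901 for miR-1198-5p, 0.0414 for miR-335-5p, 0.0482 for miR-212-3p, 0.00734 for miR-146b-5p, -0.19 for miR-134-5p, 0.0184 for miR-34a-5p, -0.27 for miR-124-3p, 0.0833 for miR-126a-3p and -0.14 for miR-204-5p. Median-of-ratios scaling gave 0.0445 for miR-486a-5p/486b-5p and 0.10 for miR-210-3p, and quantile normalization 0.16 for miR-210-3p. Leaving out a library gave -0.0660 to 0.24 for miR-134-5p, -0.0594 to 0.333 for miR-124-3p, -0.262 to 0.188 for miR-486a-5p/486b-5p, -0.254 to 0.308 for miR-204-5p and -0.104 to 0.0604 for miR-210-3p.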

Other observations

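The tests of exchanged labels and of the miR-872-5p result, and the use of the activity list for the former, were chosen after the result was seen, and so were the bounds set for the splits of the samples. Both arms of the miR-21a hairpin were lower in SE libraries, where miR-21a-3p was at 0 and miR-21a-5p at 33.8 RPM. In CON libraries they stood at 9.30 and 116 RPM. The 2 arms did not fall alike, with at least 74.6-fold for miR-21a-3p, from pooled reads, and 3.44-fold for miR-21a-5p. Whether the name miR-21a-3p was lost from the SE counts was not tested. For miR-132-5p, the partner arm of miR-132-3p, levels were 39.0 RPM ± 13.3 (SD, n = 3) in SE and 37.8 RPM ± 2.87 (SD, n = 3) in CON libraries, a log2 fold change of -0.02 (SE 0.26) that did not pass in limma. Among miRNAs with a mean of at least 5 RPM in either group, miR-872-5p and miR-21a-3p were the 2 at 0 in the other group, the former in CON and the latter in SE libraries.

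The columns labelled CON are the numerator group of the authors' deposited table, so that miR-155-5p, miR-21a-5p and miR-132-3p are lower in libraries labelled SE in that table. An exchange of 1 library with 1 of the other group needs an SE library out of place, but the lowest correlation between SE libraries across miRNAs, 0.993, lay above the highest of any SE with a CON library, 0.990, and the 9 splits that undo such an exchange called 0 miRNAs by limma, with 4 to 28 at an unadjusted p under 0.05, where the split by label called 3, with 27. Other values go the opposite way, since CON replicate 2 correlated more closely with SE replicates 1 and 3 (0.989 and 0.990) than with CON replicate 1 (0.985), and the splits that move CON replicate 2 had a median absolute log2 fold change of 0.19 to 0.21 against 0.18 by label, but CON replicate 2 held miR-872-5p at 0, miR-155-5p at 111 RPM and miR-21a-3p at 7.84 RPM, far from the SE libraries in each. The names SE and CON may have been exchanged between the 2 sets of columns as a whole, and this cannot be told apart from a true difference. The list of activity-responsive miRNAs used to weigh it had an adjusted p of 0.757 by camera and decides nothing. A list lower in SE libraries would fit a true difference as well as exchanged names. A lower load of these miRNAs in vesicles after status epilepticus stays open as well and was not tested.

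miR-872-5p was at 0 in the CON libraries, against 686 reads in the SE libraries. Lower transcription or processing of the whole miR-872 precursor is argued against, as far as vesicle RNA can show it, by the partner arm miR-872-3p. Its log2 fold change, CON over SE, was 0.15 in the authors' deposited table (95% interval -0.58 to 0.88). This arm lay near the filter, at 10.4 RPM in SE and 12.5 RPM in CON libraries. The libraries hold vesicle RNA and not brain RNA, so they cannot tell transcription in CON brain from loading into vesicles. Names missing from the count table of the CON group could also leave a 0. miR-872-5p was the 1 miRNA with a mean of at least 5 RPM in SE and, after the names were put back, 0 in all CON libraries. The loss of a single name cannot be told apart from a difference in the arm itself. A strain variant in the mature sequence was not tested.

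The 10 splits of the 6 samples are too few for a share under 0.05. The split by label called 3 miRNAs and the highest other split 0, so that 1 of 10 splits had at least as many. For lists the split by label called 0 by camera and the highest other split 2. That 10 of 10 splits had at least as many lists is fixed by the count of 0 and shows nothing about chance.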
